A study of Mus musculus with 12 samples.

How the data were processed

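RNA of mouse embryonic fibroblasts was measured on 12 Agilent single-colour arrays, 3 for each of 4 groups: wild-type and GADD34ΔC/ΔC (ΔC) cells, each untreated or transfected for 6 h with high molecular weight poly(I:C) at 2.5 µg/ml. Per the labels' protocols, poly(I:C) was given with a lipid reagent, cells were lysed with NP40, RNA was purified from the supernatant of a short spin, and 200 ng per sample was amplified and labelled with Cy3. No sample given the lipid alone is listed in the labels. Per the file headers, the scans were read with Feature Extraction 10.7.3.1, and each deposited scanner file gives the intensity of 62976 spots, background-subtracted and spatially detrended, with low values replaced by small positive surrogates and with no normalization between arrays. The same files hold, per the file headers, the median spot intensity, the median local background intensity and flags for spots well above background, saturated or uneven. The authors also deposited a table of log2 values, 1 per probe, whose 12 columns share a median of 5.28 and a highest value of 19.1, and per the submitters' processing notes limma was used, with no version or steps given.

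Values were computed from the scanner files. The log2 of the processed intensity was taken and the spots of a probe were averaged. The 75th percentile of each array over the 55681 probes was then subtracted. Over the 59305 non-control spots that percentile was 752.6 to 1117 before the log, which was not the value subtracted. Control spots and outlier spots (91 to 163 per array) were left out, and 0 spots were saturated. The files give accessions and no gene names, so that 27235 of 55681 probes were named through RefSeq accessions in the reference table, and 28446 were left unnamed. Genes were tested when a probe was well above background on all 3 arrays of at least 1 group, and the probe with the highest mean over the 12 arrays stood for its gene, which gave 15445 genes. An outlier flag on every spot of an array left out 107 probes. Of 3993 genes with several probes, 2, 0, 6 and 7 had probes called in opposite directions in the wild-type response, the ΔC response and the genotype comparisons without and with poly(I:C). Probe positions were not given and the reference holds names only, so that no gene is placed on the genome here. Array values have no count depth, and the number of arrays limits their precision.

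The 5 contrasts were tested with limma 3.58.1 in R 4.3.3 (1 mean per group over all 12 arrays, 8 residual degrees of freedom and a prior with 2.19, two-sided, Benjamini-Hochberg over the 15445 genes, called at an adjusted p under 0.05): the response to poly(I:C) in each genotype, ΔC against wild type without and with poly(I:C), and the difference between the responses. Genes well above background on no array of a group have no defined fold there, and the text gives a bound, "at least N-fold", computed with the levels of that group raised to the lowest well-above-background signal of each array. Where 1 or 2 of the 3 arrays of a group were well above background, a change between the groups is given as fitted, and its size rests partly on background readings, as for Cmpk2, Ddx3y, Gucy1b1, Hoxb9, Hoxb13, Hoxd13, Pitx1, Ppbp, Prg4, Prxl2b, Ptgis and Tnfsf10. Errors of log2 changes are standard errors from the model, and errors of levels are SDs of 3 arrays. The 28 gene lists, some of which share members, were tested with camera of limma at a preset inter-gene correlation of 0.01, two-sided, Benjamini-Hochberg over 28 lists and 5 comparisons (140 tests), and again with an estimated correlation. A list's median is also given with members at their bound where that differs. Camera compares a list with all other genes, whose median log2 change was -0.14 in the wild-type response, -0.05 in the ΔC response, -0.06 and 0.01 between genotypes without and with poly(I:C), and 0.07 for the difference. List members with no named probe, among them Mx1, Mx2, Ifnl2 and Cxcl11, were not analysed here.

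Genes were named by a fixed rule: per comparison, the 10 called genes with the largest rise and the 10 with the largest fall among those with groups that did not overlap and at least 1 array well above background in each group (for the difference, in all 4 groups and with no overlap requirement), the 5 largest bounds in each direction, 21 fixed genes, and from each list the 2 largest rises and the 2 largest falls among called members, or the 2 largest changes where none was called. Clones, predicted genes and unnamed transcripts were left out of the first 2 parts, and smaller changes were left out of the text for length. The groups, tests, lists, naming rule and the alternatives not marked otherwise were fixed before the data were examined.

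The replicate numbers were checked for pairing before any calls were compared. The deviations of arrays from their group means correlated across genes between arrays of the same number in compared groups at 0.115 to 0.651. All lay above 0.1, and a second fit treated the numbers as pairs, with the number as a block. The main counts and p-values come from the fit without the block and are unpaired. Arrays of different numbers were not compared, and 1 shared shift of the arrays numbered 3 would also correlate those numbered 1 and 2. The check therefore cannot tell pairing from such a shift. Values with the number as a block are given where they change the call on a named gene or list, and for some list counts. The scanner files place the arrays on 5 slides and 3 scan days, and changes were also computed within the slide and the scan day that hold the groups compared. Such a slide held 2 arrays of these groups and such a scan day 3, or 6 for the difference. Genes were called with these arrays among the 12, so that a kept sign alone is close to given there and does not test the batch. Alternatives were median scaling, quantile normalization, normexp background correction (offset 50), the authors' table, no filter, a filter on all 12 arrays, the mean of a gene's probes, every probe, trend and robust variance, array weights, only the groups compared, replicate, slide and scan day as blocks, an estimated correlation and leaving out each array, and, chosen after the data were seen, unnamed probes added, the authors' table without its mismatched column and the 4 arrays numbered 3 left out. Normexp was planned on mean spot signals, which the files lack, and used median spot signals. The code was tested on simulated data, 200 of 15445 genes changed: at a log2 change of 2 it called 82.1, 80.6, 88.1, 76.1 and 59.7% of changed genes in the wild-type response, the ΔC response, the genotype comparisons without and with poly(I:C) and the difference, and at a change of 1 49.3, 44.8, 58.2, 47.8 and 31.3%, with false calls at 5.03, 6.29, 8.43, 2.63 and 6.98% of calls. The simulated values were drawn independently around 1 mean per gene, with no shared effect of replicate number, slide or scan day. These shares therefore test the code and do not give the power in the real arrays. Figures were drawn with matplotlib 3.10.9.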

Results

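Gene expression was measured in mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos, on 12 Agilent single-colour arrays. The cells were wild type or GADD34ΔC/ΔC, here written ΔC. The name stands for a shortened product of Ppp1r15a, the gene for GADD34, which brings protein phosphatase 1 to the translation factor eIF2α. Each genotype was left untreated or transfected for 6 h with poly(I:C), a synthetic double-stranded RNA that cells sense as they sense viral RNA. Each of the 4 groups held 3 arrays from separate experiments, whose number limits the precision of every value. Between 60.4 and 67.3% of 55681 probes lay well above background on each array, and 15445 genes were tested. Across genes, which are not independent replicates, levels correlated at r of 0.98 to 0.996 between arrays of a group and at 0.911 to 0.99 between arrays of different groups. The first principal component (55.5% of the variance) parted the genotypes and the second (22% of the variance) parted treated from untreated arrays. The third (8.52% of the variance) parted the 4 arrays numbered 3, at 24.3 to 45.6, from the other 8, at -31 to -2.08.

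Ppp1r15a, the targeted gene, parted the genotypes on every array. Its normalized log2 level was 2.88 ± 0.42 (SD, n = 3) in untreated and 5.81 ± 0.02 in treated wild-type cells, against -7.09 ± 1.28 in untreated and -6.49 ± 2.10 in treated ΔC cells. The wild-type arrays numbered 1 to 3 read 2.65, 2.62 and 3.36 untreated and 5.79, 5.83 and 5.81 after poly(I:C). The ΔC arrays read -7.22, -8.3 and -5.75 untreated and -4.12, -8.14 and -7.2 after poly(I:C). The transcript was well above background on all 6 wild-type arrays, on no untreated ΔC array and on 1 treated ΔC array, and lay at least 486-fold lower in untreated ΔC than in untreated wild-type cells (limma adjusted p = 6.15e-05). In wild-type cells its log2 fold change with poly(I:C) was 2.93 ± 0.91 (SE, pooled over all 4 groups, the ΔC groups near background included), which did not pass the test (limma adjusted p = 0.0805). It passed with only the groups compared (adjusted p = 0.00196), normexp (1.13e-05), array weights (0.012), median scaling (0.043), the authors' table without its mismatched column (0.0026) and without ΔC poly(I:C) 1 (0.0174), over a range of 1.13e-05 to 0.553 for all alternatives. The labels do not locate the deletion or the probe, so that the signal checks which arrays are ΔC and not what the ΔC transcript holds.

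**Figure D1:**
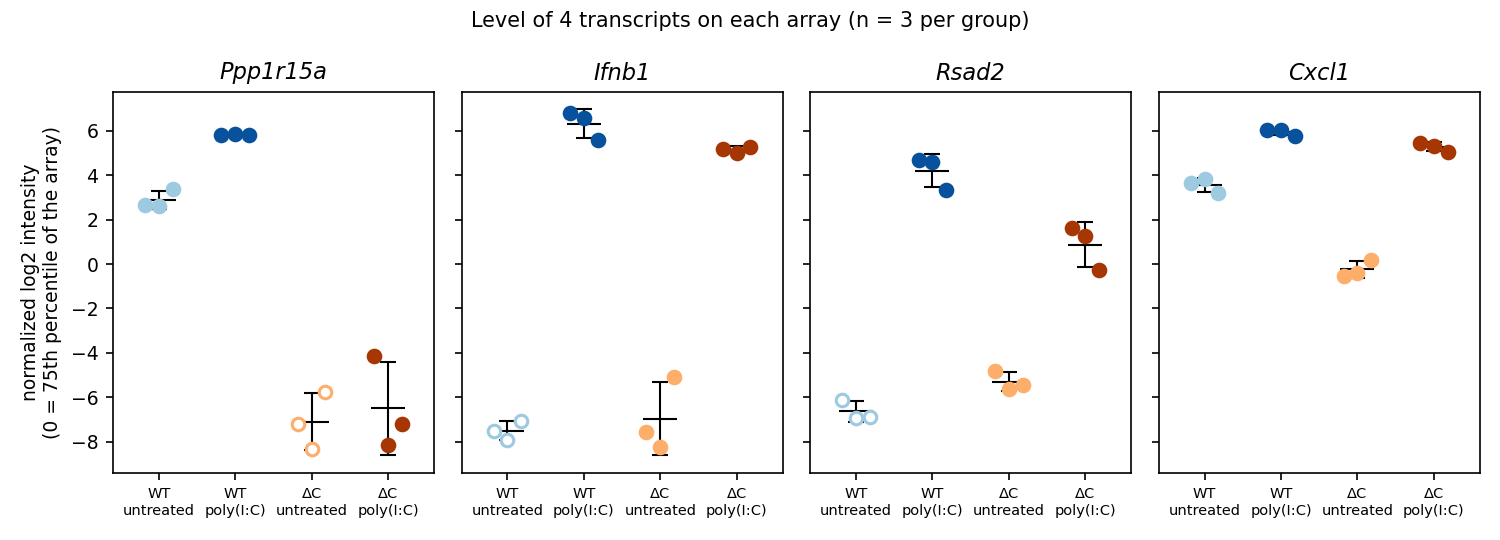
Normalized log2 level of Ppp1r15a, Ifnb1, Rsad2 and Cxcl1 on each of the 12 arrays by group (points), with the group mean (line) and SD (bars), where open points mark groups in which the gene was well above background on no array. Ppp1r15a lay at 2.62 to 5.83 on the wild-type arrays and at -8.3 to -4.12 on the ΔC arrays.

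The first comparison asked how wild-type cells respond to transfected poly(I:C). Most interferon genes, interferon-stimulated genes and cytokines tested rose. Ifnb1, which encodes interferon beta, was well above background on no untreated array and was at least 4930-fold higher after poly(I:C) (n = 3 per group, limma adjusted p = 3.04e-06). Ifna4, an interferon alpha gene, was at least 280.5-fold higher. Il6, the gene of a cytokine of the acute phase response, was at least 1068-fold and the chemokine gene Ccl4 at least 1795-fold higher. Rsad2, which encodes the antiviral enzyme viperin, was at least 1134-fold higher.

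Of 13 interferon genes tested, 12 rose (12 adjusted over the list alone), with a median log2 fold change of 3.85 (camera adjusted p = 3.45e-17, adjusted p = 0.161 with an estimated correlation). Of 55 interferon-stimulated genes, 54 rose (55 adjusted over the list alone), with a median log2 fold change of 4.83, or 4.60 with 2 members at the bound (camera adjusted p = 1.33e-70, adjusted p = 0.0968 with an estimated correlation). Among these, the log2 fold change was 8.75 ± 0.88 for Cmpk2, a nucleotide kinase gene next to Rsad2, 8.53 ± 0.47 for Ifit1, whose product binds foreign RNA, 7.83 for Usp18, whose product removes ISG15 from proteins, and 5.64 ± 0.31 for Isg15. Of 23 cytokines and chemokines, 16 rose (19 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 3.37, or 2.82 with 6 members at the bound (camera adjusted p = 1.59e-25, adjusted p = 0.0573 with an estimated correlation). Cxcl10 rose by 6.87 ± 0.22 and Ccl5, whose product attracts T cells, by 5.78. Of 29 genes of double-stranded RNA sensing and signalling, 16 rose (18 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 1.71 (camera adjusted p = 5.78e-15, adjusted p = 0.0968 with an estimated correlation). They included the RNA sensor gene Ifih1 (6.31), the transcription factor gene Irf7 (5.92) and Eif2ak2 (3.30 ± 0.45), the gene for PKR, which phosphorylates eIF2α in the presence of double-stranded RNA.

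Of 27 NF-kB targets, 18 rose (24 adjusted over the list alone), with a median log2 fold change of 1.36, or 1.35 with 2 members at the bound (camera adjusted p = 5.39e-20, adjusted p = 0.0499 with an estimated correlation and 0.108 with the replicate block as well). The adhesion molecule gene Icam1 was at least 8.86-fold higher, and Tnfaip3, a brake on NF-kB, rose by 3.82 ± 0.25. Of 26 immediate-early genes, 17 rose (22 adjusted over the list alone), with a median log2 fold change of 1.42 (camera adjusted p = 1.13e-21, adjusted p = 0.0968 with an estimated correlation). Egr2 rose by 3.30 ± 0.22, Zfp36, whose product destabilizes cytokine transcripts, by 2.85, and Fos by 2.55 ± 0.26. Of 23 genes of MHC class I presentation and the immunoproteasome, 16 rose (20 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 2.10 (camera adjusted p = 3.45e-17, adjusted p = 0.173 with an estimated correlation). The checkpoint ligand gene Cd274 rose by 7.54 and Nlrc5, an activator of class I genes, by 5.18. Of 32 cell death regulators, 8 rose (16 rose and 2 fell adjusted over the list alone, 13 rose and 1 fell with the replicate number as a block), with a median log2 fold change of 0.51 (camera adjusted p = 1.05e-05, adjusted p = 0.159 with an estimated correlation). The death ligand gene Tnfsf10 was at least 51.3-fold higher, and Zbp1, a sensor of Z-form nucleic acid, rose by 5.23. Of 48 targets of the integrated stress response, the program downstream of eIF2α phosphorylation, 7 rose (14 adjusted over the list alone), with a median log2 fold change of 0.23 (camera adjusted p = 2.62e-08, adjusted p = 0.173 with an estimated correlation). Atf3, the gene of a stress-induced transcription factor, led them (5.61 ± 0.45). Ddit3, the gene for CHOP, rose by 1.18 (limma adjusted p = 0.0166). That call was lost without wild-type untreated 1 or 2 (adjusted p = 0.059 and 0.0715) or wild-type poly(I:C) 1 or 2 (0.0872 and 0.0857), with slide (0.164) or scan day (0.0639) as a block and with the authors' table (0.142). Atf4 did not pass (0.35, adjusted p = 0.0962, and 0.0378 without wild-type poly(I:C) 3), and neither did the endoplasmic reticulum chaperone gene Hspa5 (0.07, adjusted p = 0.738). Of 25 genes of cholesterol synthesis, 2 fell (8 adjusted over the list alone), with a median log2 fold change of -0.54 (camera adjusted p = 5.55e-06, adjusted p = 0.516 with an estimated correlation).

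In total, 809 genes rose and 237 fell (limma, Benjamini-Hochberg), 605 and 34 of them by 2-fold or more, and 4728 genes (30.6%) had groups that did not overlap, against 10% by chance. The rises were 77.3% of the calls, and 97.7% with each array scaled to its median. Among called genes well above background on at least 1 array of each group and with groups that did not overlap, Narf fell most, whose product binds the nuclear lamina (-2.26 ± 0.39, adjusted p = 0.00699). That call was lost with slide (0.168) or scan day (0.0639) as a block, with only the groups compared (0.0565) and with the authors' table (0.0524). Without wild-type untreated 1 or 2 or wild-type poly(I:C) 1 or 2, 439, 473, 372 and 389 genes rose and 7, 9, 2 and 4 fell. The falls numbered 1138 and 889 without wild-type untreated 3 or poly(I:C) 3, and 104, 70, 113 and 89 without ΔC untreated 1 or 2 or ΔC poly(I:C) 1 or 2. Without all 4 arrays numbered 3, which stood apart on the third component, 2001 genes rose and 3262 fell. With slide as a block, 222 genes rose and 10 fell. The 1046 genes, called partly on these same arrays, all kept their sign within the slide (2 arrays) and within the scan day (3 arrays) that held both groups. The median over interferon-stimulated genes was 5.62 and 5.49 there, and 4.66 with slide and 4.91 with scan day as a block. The labels list no sample given lipid alone, so that lipid and RNA were not compared apart.

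The second comparison made the same measurement in ΔC cells, and there, too, some of the interferon, cytokine and interferon-stimulated genes rose. Ifnb1 had a fitted rise of 12.11 ± 0.67 on the log2 scale (SE, n = 3 per group, limma adjusted p = 1.28e-05), whose size rests partly on background readings, since only 1 of the untreated arrays (-7.54, -8.24 and -5.1) was well above background. Il6 rose by 7.95 ± 0.39, Rsad2 by 6.15 ± 0.52 and Ifit1 by 5.44 ± 0.47. Ccl4 was at least 165-fold, Ifna4 at least 71.1-fold and Cxcl2, the gene of a neutrophil chemokine, at least 34.5-fold higher than in untreated ΔC cells, where none of these 3 was well above background on any array. Cxcl1, the gene of another neutrophil chemokine, rose 45.8-fold (log2 fold change 5.52 ± 0.22, adjusted p = 1.15e-06).

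Of 13 interferon genes, 5 rose (9 adjusted over the list alone), with a median log2 fold change of 2.24 (camera adjusted p = 8.87e-16, adjusted p = 0.161 with an estimated correlation). Of 55 interferon-stimulated genes, 29 rose (46 adjusted over the list alone, 39 with the replicate number as a block), with a median log2 fold change of 2.54, or 2.48 with 2 members at the bound (camera adjusted p = 2.69e-52, adjusted p = 0.12 with an estimated correlation). Oasl1 rose by 5.15, the guanylate-binding protein gene Gbp3 by 4.93 and Isg15 by 3.71 ± 0.31. Of 23 cytokines and chemokines, 15 rose (18 adjusted over the list alone), with a median log2 fold change of 2.56, or 2.01 with 5 members at the bound (camera adjusted p = 1.58e-33, adjusted p = 0.0428 with an estimated correlation and 0.1 with the replicate block as well). Cxcl10 rose by 4.64 ± 0.22 and Ccl5 by 4.61. Of 27 NF-kB targets, 13 rose (20 adjusted over the list alone), with a median log2 fold change of 1.32 (camera adjusted p = 5.51e-27, adjusted p = 0.0376 with an estimated correlation and 0.0923 with the replicate block as well). Tnfaip3 rose by 3.52 ± 0.25. Of 26 immediate-early genes, 12 rose (22 adjusted over the list alone), with a median log2 fold change of 1.36 (camera adjusted p = 7.97e-33, adjusted p = 0.0499 with an estimated correlation and 0.1 with the replicate block as well). Egr1 rose by 2.75 ± 0.21 and its relative Egr4 by 5.56. Of 29 genes of double-stranded RNA sensing and signalling, 7 rose (10 adjusted over the list alone), with a median log2 fold change of 0.51 (camera adjusted p = 1.36e-09, adjusted p = 0.161 with an estimated correlation). Ifih1 rose by 3.33, a call lost with slide as a block (adjusted p = 0.106). Eif2ak2 did not pass (1.20, adjusted p = 0.366, and 0.0329 without ΔC poly(I:C) 3).

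Of 48 targets of the integrated stress response, 2 rose (9 adjusted over the list alone, 1 rose with the replicate number as a block), with a median log2 fold change of 0.26, or 0.23 with 1 member at the bound (camera adjusted p = 1.93e-09, adjusted p = 0.161 with an estimated correlation). Atf3 rose by 4.29 ± 0.45, a call lost with slide as a block (adjusted p = 0.117). Ddit3 did not pass (1.08, adjusted p = 0.0533, and 0.0399 without wild-type poly(I:C) 3 and 0.0104 without ΔC untreated 3). Of 23 genes of MHC class I presentation and the immunoproteasome, 1 rose (1 adjusted over the list alone), with a median log2 fold change of 0.35 (camera adjusted p = 0.00747, adjusted p = 0.764 with an estimated correlation, 0.185 without ΔC untreated 3, 0.0965 without ΔC poly(I:C) 1, 0.87 with slide and 0.372 with scan day as a block and 0.0503 with no filter). The member that rose was Cd274 (3.03, adjusted p = 0.0177). That call was lost without ΔC untreated 1 or 2 (adjusted p = 0.0824 and 0.0782) or ΔC poly(I:C) 1 or 2 (0.0852 and 0.0862), with slide (0.226) or scan day (0.0897) as a block and with only the groups compared (0.0743). Of 32 cell death regulators, 0 passed limma's test, 2 did with the replicate number as a block and 4 had an unadjusted p under 0.05. Their median log2 fold change was 0.09, or 0.08 with 2 members at the bound and -0.05 with each array scaled to its median (camera adjusted p = 0.0295, adjusted p = 0.491 with an estimated correlation). This call was lost without ΔC untreated 3 (0.307) or ΔC poly(I:C) 1 or 2 (0.0891 and 0.107), with slide (0.312) or scan day (0.159) as a block, with no filter (0.115) and with array weights (0.0611). Of 25 genes of cholesterol synthesis, 0 passed limma's test and 4 had an unadjusted p under 0.05, with a median of -0.35 (camera adjusted p = 2.92e-07, adjusted p = 0.491 with an estimated correlation).

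In total, 281 genes rose and 3 fell (limma, Benjamini-Hochberg), 257 and 2 of them by 2-fold or more, and 2733 genes (17.7%) had groups that did not overlap, against 10% by chance. The 3 falls were those of Gucy1b1 (-1.72), a subunit of soluble guanylate cyclase, Celf5 (-0.89) and Ccdc160 (at least 1.267-fold lower). With the replicate number as a block, the calls on Gucy1b1 (adjusted p = 0.0544) and Celf5 (0.0777) were lost and 4 genes fell. The call on Gucy1b1 was lost without any 1 array (adjusted p = 0.0559 to 0.167) other than wild-type poly(I:C) 3, ΔC untreated 3, ΔC poly(I:C) 1 or ΔC poly(I:C) 3. That on Celf5 was lost without any (0.0574 to 0.19) other than the first 2 and the last of these. That on Ccdc160 was lost without any (0.0572 to 0.201) other than wild-type untreated 3 or ΔC poly(I:C) 3. All 3 calls (in the same order) were also lost with slide as a block (0.119, 0.256 and 0.221), with no filter (0.054, 0.0612 and 0.066), with trend and robust (0.112, 0.0617 and 0.323) and with only the groups compared (0.237, 0.215 and 0.157) and with the authors' table (0.368, 0.409 and 0.237). Without that table's mismatched column the calls on Gucy1b1 (0.069) and Celf5 (0.194) were lost. The call on Gucy1b1 was also lost with median scaling (0.0524), quantile normalization (0.0902) and normexp (-0.26, adjusted p = 0.46). That on Celf5 was lost with median scaling (0.136), the mean of a gene's probes (0.199) and scan day as a block (0.0866). That on Ccdc160 was lost with scan day as a block (0.0782) and normexp (adjusted p = 0.712). Without ΔC untreated 1 or 2 or ΔC poly(I:C) 1 or 2, 162, 154, 160 and 159 genes rose. Leaving out any 1 of the 12 arrays moved the number of falls by over 1.5 times. It was 0 without wild-type poly(I:C) 2, ΔC untreated 2 or ΔC poly(I:C) 2 (limma, 1439, 1018 and 1173 genes at an unadjusted p under 0.05), 1 without array 1 of any group or wild-type untreated 2, and 5, 11, 32 and 15 without array 3 of wild-type untreated, wild-type poly(I:C), ΔC untreated and ΔC poly(I:C). Without all 4 arrays numbered 3, 1007 genes rose and 1022 fell. With slide as a block, 84 genes rose and 0 fell. The 284 genes, called partly on these same arrays, all kept their sign within the slide (2 arrays) and within the scan day (3 arrays) that held both groups. The median over interferon-stimulated genes was 2.83 and 2.88 there, and 2.42 with slide and 2.68 with scan day as a block.

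Set side by side, most rises went the same way. Across all 15445 genes the log2 fold changes of the genotypes, which share no array, correlated at Pearson's r = 0.74 and Spearman's rho = 0.559, with a slope of 0.517 for ΔC on wild type. Of the 809 genes that rose in wild-type cells, 753 also had a log2 fold change above 0 in ΔC cells and 714 had a smaller one, with medians of 1.72 in wild-type and 0.803 in ΔC cells. Choosing genes for a wild-type rise tends to favour a smaller one in ΔC cells. Of the 281 genes that rose in ΔC cells, 280 had a log2 fold change above 0 in wild-type cells and 153 a smaller one in ΔC cells, with medians of 2.37 and 2.4, so that the 2 choices do not give one picture of size. The rises called in both numbered 242, against 14.7 for independent lists of that size, and the falls called in both 0, against 0.046. Interferon-stimulated genes that rose in wild-type cells kept a median of 50.9% of their wild-type log2 change in ΔC cells, those of MHC class I presentation 20.5% and interferons 58.6%. Immediate-early genes kept 87.9%, cytokines and chemokines 82.3% and NF-kB targets 81.9%, shares that the same choice tends to lower.

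**Figure D2:**
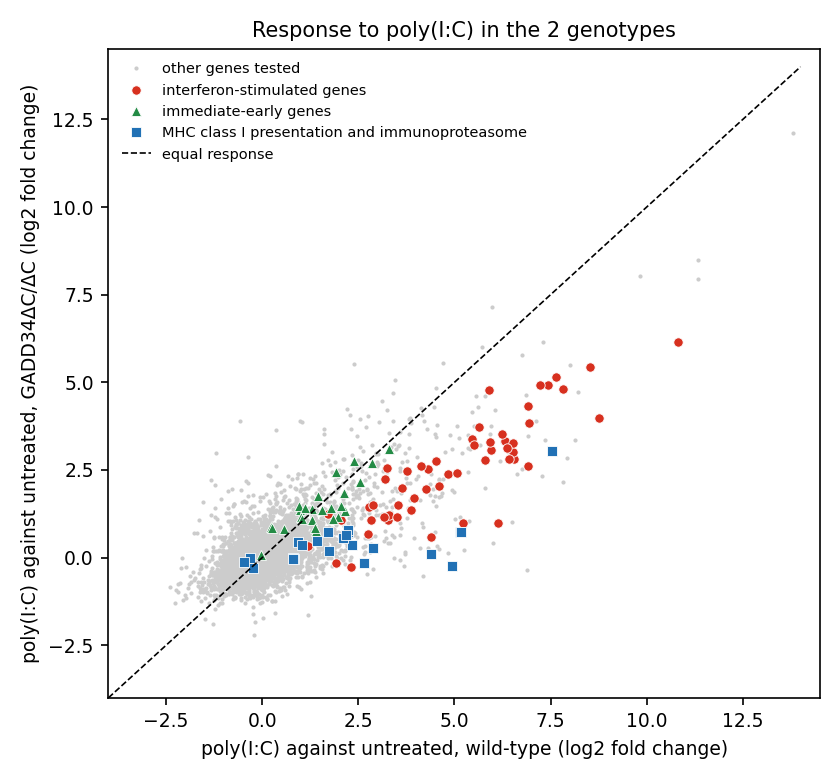
Log2 fold change with poly(I:C) of each of the 15445 genes in wild-type cells (x axis) and in ΔC cells (y axis), with interferon-stimulated genes, immediate-early genes and genes of MHC class I presentation marked and a dashed line at equal responses. All 55 interferon-stimulated genes lie below the dashed line, with medians of 4.83 in wild-type and 2.54 in ΔC cells, and the immediate-early genes lie around it, with medians of 1.42 and 1.36.

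The difference between the responses was tested as the interaction of genotype and treatment. The estimated response of all 55 interferon-stimulated genes was lower in ΔC than in wild-type cells, with a median log2 difference of -2.44 (camera adjusted p = 1.47e-64, adjusted p = 0.0968 with an estimated correlation). Of these, 0 passed limma's test over all genes, 49 passed adjusted over the list alone, 12 passed with the replicate number as a block and 49 had an unadjusted p under 0.05. Rsad2, for example, whose wild-type rise has only a lower bound, did not pass (adjusted p = 0.184, 0.0136 with the block and 0.00896 without wild-type poly(I:C) 3). Isg15 did not pass either, with a difference of -1.93 ± 0.44 (adjusted p = 0.345, 0.0417 with the block and 0.0286 without wild-type poly(I:C) 3). The 23 genes of MHC class I presentation had a median of -1.51 (camera adjusted p = 2.76e-24, adjusted p = 0.12 with an estimated correlation), where 0 passed over all genes, 15 adjusted over the list alone and 5 with the block, and 18 had an unadjusted p under 0.05. The level of Psmb9, an immunoproteasome subunit, went from -2.89 ± 0.18 to 2.04 ± 1.27 (log2, SD) in wild-type and from 1.56 ± 0.71 to 1.31 ± 0.38 in ΔC cells, a difference of -5.18 ± 0.79 (adjusted p = 0.174, 0.0171 with the block and 6.81e-04 without wild-type poly(I:C) 3). Interferons had a median difference of -1.70 (camera adjusted p = 5.41e-09, adjusted p = 0.34 with an estimated correlation), although Ifnb1, whose wild-type rise has only a lower bound, did not pass (adjusted p = 0.987). Genes of double-stranded RNA sensing had a median of -0.95 (camera adjusted p = 6.06e-13, adjusted p = 0.12 with an estimated correlation), cell death regulators of -0.26 (camera adjusted p = 2.86e-05, adjusted p = 0.161 with an estimated correlation) and cytokines and chemokines of -0.51 (camera adjusted p = 6.39e-04, adjusted p = 0.508 with an estimated correlation and 0.114 with the filter on all 12 arrays). Immediate-early genes had a median of -0.04 (camera adjusted p = 0.55, 0.036 without wild-type untreated 3) and targets of the integrated stress response of -0.06 (camera adjusted p = 0.231, 0.00981 without wild-type untreated 3).

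In total, 3 genes passed (limma, Benjamini-Hochberg), 1 with a larger and 2 with a smaller response in ΔC cells, against 4 and 37 with the replicate number as a block. Cxcl1 rose by 2.39 ± 0.22 in wild-type and by 5.52 ± 0.22 in ΔC cells, a difference of 3.13 ± 0.31 (adjusted p = 0.0176). Its untreated level was 13.9-fold lower in ΔC cells (adjusted p = 3.53e-06) and its treated level differed by -0.67 on the log2 scale (adjusted p = 0.053). That difference passed without wild-type untreated 3 (0.0366), ΔC untreated 3 (0.0251) or the arrays numbered 3 (0.00521), and with normexp (0.0365), the filter on all 12 arrays (0.0496), trend and robust (0.0321), array weights (0.00198) and only the groups compared (0.0356). Fbxo15, which encodes an F-box protein, rose 7.67-fold in wild-type cells (adjusted p = 1.78e-05) and had a log2 fold change of 0.33 in ΔC cells (adjusted p = 0.58), a difference of -2.61 ± 0.28 (adjusted p = 0.018). Gbp2b, a guanylate-binding protein gene that was named after its values were seen, rose 117-fold in wild-type cells (adjusted p = 1.43e-04) and was well above background on no ΔC array, so that its ΔC response and the size of the difference are not defined (adjusted p = 0.0483 from the fitted levels). The call on Cxcl1 was lost without wild-type poly(I:C) 1 or 2 (adjusted p = 0.0893 and 0.0855), ΔC untreated 1 or 2 (0.0706 and 0.0616) or ΔC poly(I:C) 1 or 2 (0.0937 and 0.0532). That on Fbxo15 was lost without those 6 (in the same order 0.105, 0.0965, 0.0741, 0.0616, 0.0937 and 0.0687) and without wild-type untreated 3 (0.0631) or ΔC untreated 3 (0.069). That on Gbp2b was lost without the same 8 (0.191, 0.178, 0.151, 0.229, 0.209, 0.109, 0.0821 and 0.157) and without wild-type untreated 1 or 2 (0.124 and 0.137). All 3 calls, on Cxcl1, Fbxo15 and Gbp2b, were lost with slide (0.201, 0.346 and 0.302) and with scan day as a block (0.122, 0.241 and 0.241), with the authors' table (0.826, 0.234 and 0.35) and with that table without its mismatched column (0.0599, 0.203 and 0.0911). That on Fbxo15 was also lost with median scaling (0.0694), quantile normalization (0.163) and trend and robust (0.0612), and that on Gbp2b with no filter (0.0665) and with the unnamed probes added (0.0601). Leaving out wild-type poly(I:C) 3 gave 10 larger and 200 smaller responses, and leaving out all 4 arrays numbered 3 gave 94 and 360, among them 41 interferon-stimulated genes and 19 genes of MHC class I presentation, all smaller in ΔC cells. Without wild-type poly(I:C) 1 or 2, ΔC untreated 1 or 2 or ΔC poly(I:C) 1, 0 genes passed (limma, 566, 550, 675, 608 and 807 at an unadjusted p under 0.05). The larger and smaller responses numbered 1 and 0 without ΔC untreated 3 or ΔC poly(I:C) 2, 1 and 1 without wild-type untreated 2, 2 and 0 without wild-type untreated 3, and 2 and 3 without ΔC poly(I:C) 3. Within the scan day that held all 4 groups the median difference over interferon-stimulated genes was -2.20, and no slide held all 4 groups.

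The third comparison asked how the genotypes differ at rest. HOX genes, the transcription factor genes that mark position along the body and limb axes, differed in both directions. Hoxc9 was at least 315-fold and Hoxb2 at least 194-fold higher in ΔC cells, and Hoxb13 and Hoxb9 were higher by 9.37 and 9.37 on the log2 scale (n = 3 per group). The log2 difference of Hoxd13, a gene of the distal limb, was -11.22 ± 0.59 (limma adjusted p = 2.12e-06). That of Pitx1, which marks the hindlimb, was -11.35 ± 0.84 (adjusted p = 1.67e-05). Of 34 HOX genes, 21 were higher and 6 were lower (22 and 6 adjusted over the list alone), with a median log2 difference of 2.59 (camera adjusted p = 1.59e-10, adjusted p = 0.0125 with an estimated correlation and 0.0923 with the replicate block as well). All 9 HOXB genes tested and 8 of 9 HOXC genes were higher, 4 of 5 HOXD genes were lower, and of 11 HOXA genes 4 were higher and 2 lower.

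**Figure D3:**
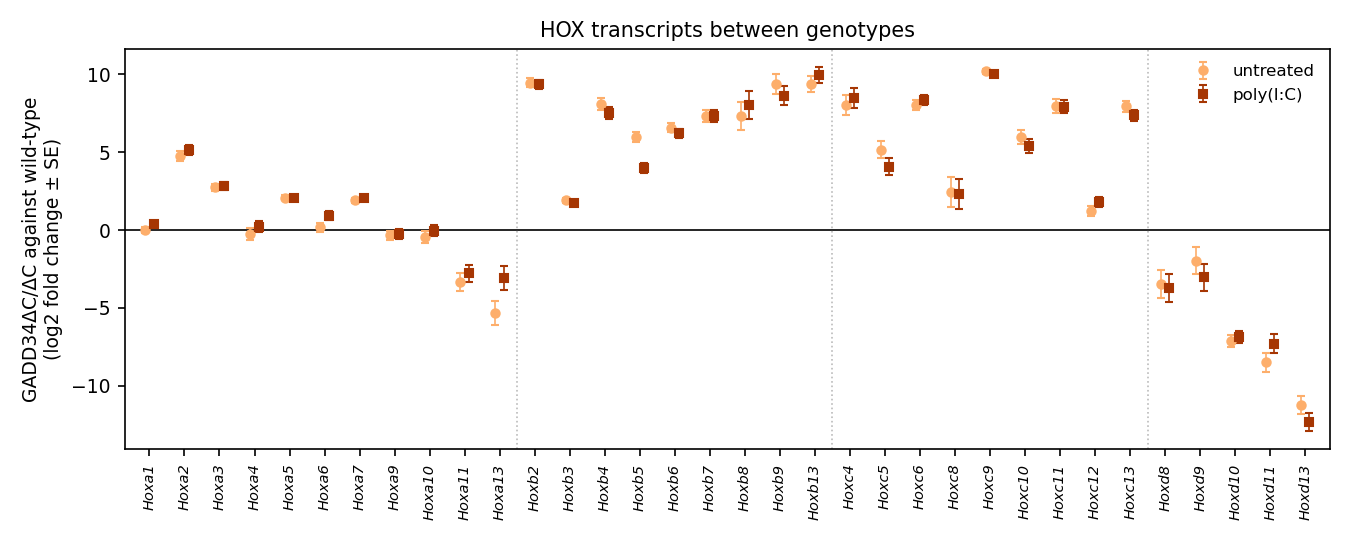
Log2 difference between ΔC and wild-type cells (y axis, bars SE) of the 34 HOX genes tested (x axis), untreated (circles) and after poly(I:C) (squares), in the order of the clusters, which dotted lines part. In untreated cells the HOXB genes lie above 0 and the HOXD genes below 0, and for 10 of the 34 genes, which were well above background on no array of 1 genotype, the point is a fitted value and no measured size.

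Other genes with large differences were Prxl2b (9.74), a prostamide synthase gene, Ptgis (8.34), the prostacyclin synthase gene, and Gas6 (7.66), which encodes a ligand of the TAM receptors, all higher in ΔC cells. Lower were the neutrophil chemokine genes Ppbp (-8.62) and Cxcl5 (-7.82 ± 0.69), the joint lubricant gene Prg4 (-7.24) and the collagen gene Col6a3 (-5.89). Of 23 genes of MHC class I presentation and the immunoproteasome, 10 were higher and 1 were lower (11 and 1 adjusted over the list alone, 2 lower with the replicate number as a block), with a median log2 difference of 0.87 (camera adjusted p = 0.00174, adjusted p = 0.687 with an estimated correlation). The immunoproteasome genes Psmb8 and Psmb9 were higher by 4.54 and 4.45. Of 55 interferon-stimulated genes, 3 were higher and 2 were lower (3 and 2 adjusted over the list alone, 9 higher with the replicate number as a block), with a median log2 difference of 0.20, or 0.21 with 3 members at the bound (camera adjusted p = 0.55). Ifih1 was higher by 2.69 (adjusted p = 0.00167), and Ifnb1, well above background on 1 ΔC and 0 wild-type arrays, did not pass (adjusted p = 0.599). Of 48 targets of the integrated stress response, which include Ppp1r15a, 1 was higher and 12 were lower (2 and 14 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.00769, adjusted p = 0.559 with an estimated correlation, 0.127 without wild-type untreated 3 and 0.0517 with scan day as a block). Gdf15, a stress-induced secreted factor, was lower (-3.58, adjusted p = 0.0652 with slide as a block). Ddit3 was lower (-1.08, adjusted p = 0.0103, 0.207 with slide and 0.0941 with scan day as a block). Of the Y-linked genes, 3 were tested. Uty was at least 4.69-fold lower in ΔC cells. Ddx3y read -8.22, -8.3 and -2.08 on ΔC untreated 1, 2 and 3 against 0.273 to 1.15 on the wild-type untreated arrays (-6.80 ± 1.86, adjusted p = 0.0271, a call lost without any 1 of these arrays except ΔC untreated 3, at 0.0554 to 0.105, and with slide or scan day as a block, at 0.176 and 0.0929).

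In total, 1686 genes were higher and 1581 lower in untreated ΔC cells (limma, Benjamini-Hochberg), 1112 and 561 of them by 2-fold or more, and 5748 genes (37.2%) had groups that did not overlap, against 10% by chance. The higher genes were 51.6% of the calls, and 64.5% with each array scaled to its median. Without ΔC untreated 1 or 2, 1014 and 1049 genes were higher, and without wild-type untreated 1 or these 2 arrays 926, 779 and 762 were lower. Without all 4 arrays numbered 3, 2752 were higher and 2873 lower. With slide as a block, 549 were higher and 374 lower. The 3267 genes, called partly on these same arrays, all kept their sign within the slide (2 arrays) and within the scan day (3 arrays) that held both groups. The median over HOX genes was 2.48 and 2.45 there, and 2.65 with slide and 2.42 with scan day as a block. The genotypes' embryos, sex and passage are not given, so that the allele cannot be told apart from the culture here.

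The last comparison set the genotypes side by side after poly(I:C), where 44 of 55 interferon-stimulated genes, 10 of 13 interferons and 8 of 23 genes of MHC class I presentation were called lower in ΔC cells. None of these 3 list calls held with an estimated correlation (camera, adjusted p = 0.34, 0.496 and 0.661). The log2 difference was -5.16 ± 0.64 for Zbp1 (SE, n = 3 per group, limma adjusted p = 5.17e-04), -5.37 ± 0.55 for Phf11d, -5.55 ± 0.98 for Tnfsf10 and -3.33 ± 0.52 for Rsad2 (adjusted p = 0.00173). Gbp2b was at least 699.9-fold lower. Cxcl10 was lower (-1.35 ± 0.22, adjusted p = 0.0023), whereas Ifnb1 (-1.17 ± 0.67, adjusted p = 0.251, and 0.0365 without ΔC untreated 3) and Il6 (-0.86 ± 0.39, adjusted p = 0.143, and 0.00136 without wild-type poly(I:C) 3) did not pass.

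Of 55 interferon-stimulated genes, 44 were lower (52 adjusted over the list alone, 52 with the replicate number as a block), with a median log2 difference of -2.16 (camera adjusted p = 5.13e-22, adjusted p = 0.34 with an estimated correlation). Of 13 interferon genes, 10 were lower (11 adjusted over the list alone), with a median log2 difference of -2.13 (camera adjusted p = 2.01e-05, adjusted p = 0.496 with an estimated correlation). Ifna7 had a difference of -2.76 (adjusted p = 0.0101, and 0.0906 with slide as a block and 0.0527 with only the groups compared). Of 23 genes of MHC class I presentation and the immunoproteasome, 8 were lower (8 adjusted over the list alone), with a median log2 difference of -0.59 (camera adjusted p = 4.29e-04, adjusted p = 0.661 with an estimated correlation). Cd274 was lower (-2.86, a call lost with slide as a block at 0.0625). Of 23 cytokines and chemokines, 4 were higher and 12 were lower (4 and 16 adjusted over the list alone), with a median log2 difference of -0.91 (camera adjusted p = 5.39e-04, adjusted p = 0.505 with an estimated correlation). Cxcl5 lay furthest below (-6.43). Cxcl16 and Cxcl12 were higher by 1.61 and 2.19. Of 29 genes of double-stranded RNA sensing and signalling, 1 was higher and 7 were lower (3 and 12 adjusted over the list alone, 13 lower with the replicate number as a block), with a median log2 difference of -0.70 (camera adjusted p = 0.00393, adjusted p = 0.516 with an estimated correlation). Eif2ak2 did not pass (-1.31, adjusted p = 0.0638, 0.0214 with the replicate number as a block and 0.0443 without wild-type poly(I:C) 3). Of 27 NF-kB targets, 1 was higher and 4 were lower (1 and 4 adjusted over the list alone, 2 higher with the replicate number as a block), with a median log2 difference of -0.30 (camera adjusted p = 0.0424, adjusted p = 0.674 with an estimated correlation, a call lost without wild-type poly(I:C) 1 or 2 at 0.175 and 0.171 and without ΔC poly(I:C) 3 at 0.118, and with median scaling, quantile normalization and normexp at 0.0852, 0.0887 and 0.075). Cd83 was at least 25.48-fold higher, and Irf1, a transcription factor of interferon responses, was lower (-1.52, a call lost with slide as a block at 0.0804). Of 48 targets of the integrated stress response, Ppp1r15a included, 1 was higher and 12 were lower (2 and 14 adjusted over the list alone), with a median log2 difference of -0.35 (camera adjusted p = 3.26e-04, adjusted p = 0.457 with an estimated correlation). Gdf15 was lower (-4.62 ± 0.62), and so was Ddit3 (-1.18, adjusted p = 0.00694, and 0.0925 with slide as a block).

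The HOX differences seen at rest were there after poly(I:C) too. Of 34 HOX genes, 22 were higher and 7 were lower (23 and 7 adjusted over the list alone), with a median log2 difference of 2.57 (camera adjusted p = 1.1e-10, adjusted p = 0.0125 with an estimated correlation and 0.0923 with the replicate block as well). Hoxd13 was at least 1520-fold lower and Hoxb13 at least 809-fold higher, and 27 HOX genes were called the same way with and without poly(I:C). Across 15445 genes the genotype differences with and without poly(I:C), which share no array, correlated at r = 0.874 and rho = 0.735. Of the higher genes 1291 were called in both, against 200.5 for independent lists, and of the lower genes 880, against 143. Here, too, the calls share 1 spread per gene, so that the values for independent lists are a reference only. In total, 1837 genes were higher and 1396 lower in treated ΔC cells (limma, Benjamini-Hochberg), 1119 and 700 of them by 2-fold or more, and 6269 genes (40.6%) had groups that did not overlap, against 10% by chance. The higher genes were 56.8% of the calls, and 45.9% with each array scaled to its median. Without wild-type poly(I:C) 1 or 2 or ΔC poly(I:C) 1, 1050, 1058 and 1217 genes were higher, and without these or ΔC poly(I:C) 2, 696, 696, 877 and 781 were lower. Without all 4 arrays numbered 3, 3212 were higher and 2614 lower. With slide as a block, 623 were higher and 316 lower. The 3233 genes, called partly on these same arrays, all kept their sign within the slide (2 arrays) and within the scan day (3 arrays) that held both groups. The median over interferon-stimulated genes was -2.10 and -2.02 there, and -2.31 with slide and -2.13 with scan day as a block.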

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

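The tests of the starting level, of a common shrinkage, of the authors' column and of the splits that part all pairs of replicate numbers in both treatments were chosen only after the results were seen, whereas the scan day and the other splits of the samples were planned.

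The difference between the responses of the genotypes, tested as an interaction, marked 3 genes and 10 lists. The genes were Cxcl1 (3.13 log2), Fbxo15 (-2.61) and Gbp2b (-7.24, a fitted value that rests on background readings in all 6 ΔC arrays and is no measured size). Of the lists, those of the antiviral response had a median difference below 0: -2.44 for interferon-stimulated genes, -1.70 for interferons, -1.51 for MHC class I presentation, -0.95 for double-stranded RNA sensing, -0.51 for cytokines and chemokines and -0.26 for cell death regulators. With an estimated correlation 0 of the 10 lists were called (camera, adjusted p = 0.0968 to 0.674, and 0.0968, 0.34, 0.12, 0.12, 0.508 and 0.161 for these 6). The MHC class I list had a median above 0 between untreated genotypes and nearer to 0 than -1.51 between treated ones (1.03 and -0.71 within the scan day that held all groups). Its difference thus includes a higher starting level in ΔC cells. NF-kB targets had a median of -0.20, or -0.10 with 2 members at the bound (camera adjusted p = 0.0432, 0.674 with an estimated correlation, 0.0648 with the replicate number as a block and 0.0891, 0.122 and 0.206 with median scaling, quantile normalization and normexp), a call also lost without wild-type untreated 1 (0.101), wild-type untreated 2 (0.108), wild-type poly(I:C) 1 (0.397), wild-type poly(I:C) 2 (0.287), ΔC untreated 3 (0.266), ΔC poly(I:C) 1 (0.0571) or ΔC poly(I:C) 3 (0.165). Glycolysis and hypoxia genes had a median of 0.24 (camera adjusted p = 0.0287, 0.491 with an estimated correlation, 0.15 with median scaling, 0.169 with quantile normalization, 0.683 with slide and 0.591 with scan day as a block), a call also lost without wild-type untreated 1 (0.146), wild-type poly(I:C) 3 (0.36), ΔC untreated 3 (0.21), ΔC poly(I:C) 1 (0.157) or ΔC poly(I:C) 2 (0.17). Ribosomal protein genes had a median of 0.23 (adjusted p = 5.41e-09, 0.674 with an estimated correlation), but were called in the opposite direction with the slide block and with the scan day block (-0.0753 and adjusted p = 0.00437 with each). Macrophage and leukocyte markers had a median of 0.58, or 0.48 with 4 members at the bound (adjusted p = 0.00472, 0.116 with an estimated correlation).

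The smaller rise of interferon-stimulated genes in ΔC cells was weighed. A higher starting level alone would leave the treated levels alike, and between treated genotypes the list's median was -2.16. One common shrinkage of every response would take the same share from all responding genes, and the share of the wild-type median change kept by all 26 immediate-early genes exceeded that kept by all 55 interferon-stimulated genes by 0.43, and by 0.299, 0.377 and 0.432 on the arrays numbered 1 to 3. Scan day was held fixed in 1 day with all 4 groups, where the median difference was -2.20. Of 100 draws of the genotype within each treatment 1, the real one, gave a median as large (2.44 against 2.33 in the highest other), but these draws ignore the replicate numbers. The same held for 1, the real one, of the 32 splits that part all pairs of replicate numbers (2.36 in the highest other). That share, 0.0312, is the lowest that 32 splits can give. Both shares lie under 0.05. The difference is the genotype difference in treated cells less that in untreated cells, whose median was near 0 for this list. A split that keeps the treated groups together therefore stays near the real median by construction, as at 1.88 with the genotypes swapped in 1 treatment. These shares therefore cannot tell whether the smaller rise arose by chance. An effect of the allele on interferon output or signalling may account for the pattern, but a lower uptake of poly(I:C) by the ΔC culture stays open, because the lipid or serum could drive the immediate-early genes by itself and no sample is listed as given lipid alone, and so does a difference between the cultures other than the allele.

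The authors' table was marked because 1 of its columns departs from the scanner file of the same sample. The column for ΔC poly(I:C) 1 correlated at r = 0.949 with its own scanner file across probes, further from it than any of the other 11 columns from theirs, and the table gives Ppp1r15a 11.8 and Ifnb1 2.89 there, where the scanner file gives 5.64 and 14.9. A normalization would keep the order of the values, and Spearman's rho was 0.91 (1 for the other columns). A scanner file of another group under that label is excluded by its own levels, with Ppp1r15a at -6.75 against the lowest wild-type array and Ifnb1 at 10.28 above the highest untreated array (log2). The values of another array in that column are a candidate explanation: the column correlated most with a wild-type untreated array (r = 0.974), although it matched none of the 12 scanner files as closely as the other columns match theirs. The values compared in the report come from the scanner files, and the authors' table serves as an alternative.

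Other splits of the same 6 arrays into 3 and 3 called at most 6 genes in place of the 1046 of the wild-type response, 0 in place of 284 in ΔC cells (limma), and 4 and 0 in place of the 3267 and 3233 between genotypes without and with poly(I:C). In each case 1 of 10 splits, the real one, called as many, which is too few splits for a share under 0.05. Among the 4 splits that part all 3 pairs of replicate numbers, the highest other than the real one called 1 gene in the wild-type response and 0 in the other 3 comparisons (limma). For the difference, 3 of 100 draws of the genotype within each treatment called as many genes as the 3 found, the highest other draw also calling 3, but these draws ignore the replicate numbers. Of the 32 splits that part all pairs of replicate numbers in both treatments, the real one included, 3 called as many as the 3 found. The highest other, which called 5583 genes and 6564 with the number as a block, swaps the genotypes in 1 treatment and so adds up the genotype differences of both by construction, a structure of the samples. Without it 2 of 31 splits called as many as the 3 found, so that chance is not excluded for that count. With the number as a block, where 2 of 32 called as many as the 41 found and the highest other without the swap called 1, the swap alone sets the share on either side of 0.05, so that these splits decide nothing about that count.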

How the results depend on the processing

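Of the alternatives, the unnamed probes, the authors' table without its mismatched column and the 4 arrays numbered 3 left out were chosen only after the data were seen, and all others were planned. Counts are given as higher and lower. The cause of a change was not tested unless the alternative's construction shows it. None of the alternatives was left out, and the fit to the groups compared does not apply to the difference.

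With an estimated correlation 6 of 56 list calls held: NF-kB targets in both genotypes' responses, cytokines and immediate-early genes in ΔC cells, and HOX genes in both genotype comparisons. With an estimated correlation and the replicate block together 0 held (camera, adjusted p = 0.0923 to 0.108 for these 6). Median scaling gave 14 falls in wild-type cells, 696 lower genes between untreated genotypes, 999 higher genes between treated ones and 1 smaller response, and it moved the median of all genes to -0.19 in the ΔC response, -0.14 between treated genotypes and -0.14 in the difference. Quantile normalization gave 149 falls in wild-type and 7 in ΔC cells. Normexp gave 5 falls in ΔC cells and 2 and 9 in the difference. The authors' table, with 1 mismatched column, gave 344 and 8 in wild-type cells, 0 and 0 in ΔC cells (limma, 1245 at an unadjusted p under 0.05), 752 and 277 and 288 and 268 between genotypes without and with poly(I:C), 0 and 0 in the difference (limma, 902) and r = 0.417 between responses. Without that column it gave 80 falls in wild-type cells, 156 rises in ΔC cells, 893 lower genes between treated genotypes and 0 and 0 in the difference (limma, 883). No filter gave 72 falls in wild-type cells, 1 in ΔC cells, 2 and 1 in the difference and r = 0.517, with more and dimmer genes tested. The filter on all 12 arrays gave 1 fall in ΔC cells and 1 smaller response. Every probe gave 5 falls in ΔC cells, and trend and robust gave 570 falls in wild-type cells. Unnamed probes added, the ΔC response had 484 and 9 and the difference 1 smaller response. The mean of a gene's probes moved none of these counts by over 1.5 times.

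Array weights gave 2482 and 4263 in wild-type cells, 1256 and 1414 in ΔC cells, 3545 and 3863 and 3786 and 3145 between genotypes without and with poly(I:C) and 196 and 498 in the difference, with weights of 0.281 to 0.349 for the arrays numbered 3 and of 0.848 to 4.53 for the others. Those 4 arrays left out gave 2001 and 3262, 1007 and 1022, 2752 and 2873, 3212 and 2614 and 94 and 360 in the same order. Only the groups compared gave 444 and 7 in wild-type cells, 180 and 0 in ΔC cells (limma, 1737 at an unadjusted p under 0.05) and 928 lower genes between untreated genotypes, with fewer arrays to estimate the spread. The replicate block gave 942 and 338, 309 and 4, 2062 and 2155, 2190 and 1793 and 4 and 37 in the order above, and ended 4 list calls. The slide block gave 222 and 10, 84 and 0, 549 and 374, 623 and 316 and 0 and 0 (limma, 999 at an unadjusted p under 0.05) in the order above and r = 0.497, and the scan day block 480 and 49, 144 and 1, 898 and 728, 1072 and 667 and 0 and 0 (limma, 882) and r = 0.523. Leaving out 1 array gave 372 to 1193 rises and 2 to 1138 falls in wild-type cells, 154 to 345 and 0 to 32 in ΔC cells, 1014 to 1912 and 762 to 1906 between untreated and 1050 to 2003 and 696 to 1541 between treated genotypes, 0 to 10 and 0 to 200 in the difference, r of 0.659 to 0.742 and 49 to 61 list calls.

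Ribosomal protein genes, relative to all other genes, turned from lower to higher in wild-type cells and from higher to lower in ΔC cells and in the difference under the alternatives named here. Their median in wild-type cells was then -0.0134 with quantile normalization, -0.0131 with the authors' table with or without its column, -0.0303 with the slide and -0.00278 with the scan day block, and 0.0191 without the arrays numbered 3. In ΔC cells it was -0.0298 with the authors' table, -0.11 with the slide and -0.0727 with the scan day block (called, adjusted p = 1.11e-04 and 0.0247), and in the difference -0.015, -0.0753 and -0.0753 there (called with both blocks, adjusted p = 0.00437 with each) and 0.00789 without the column. MHC class I genes in ΔC cells had -0.0981 with the authors' table. No called named gene changed direction under any alternative. Of those that did not pass, Hspa5 in wild-type cells ranged from -0.0262 to 0.173 and changed sign with the slide block and without wild-type untreated 1, and Ifnb1 between untreated genotypes, near background, changed sign with normexp, array weights, without ΔC untreated 3 and without the arrays numbered 3. Of 111 results on named genes, the direction was kept and the call changed as follows: 3 lost and 1 gained with median scaling, 2 lost and 1 gained with quantile normalization, 2 lost and 4 gained with normexp, 42 lost and 1 gained with the authors' table, 18 lost and 1 gained with the slide block, 10 lost with the scan day block, 2 lost and 4 gained with the replicate block, 4 lost and 4 gained with trend and robust, 11 gained with array weights, 10 gained without the arrays numbered 3, 6 lost and 2 gained with the authors' table without its column, 4 lost with no filter and 1 lost each with the mean of a gene's probes and the unnamed probes added, none with every probe, 6 lost and 2 gained of 104 with only the groups compared, 1 gained of 66 with the filter on all 12 arrays, and 0 to 8 lost and 0 to 7 gained without 1 array. Of 140 list results the calls lost and gained with the direction kept were 8 and 2 with median scaling, 11 and 1 with quantile normalization, 3 and 3 with normexp, 13 and 6 with the authors' table and 15 and 2 without its column, 6 and 2 with no filter, 1 and 0 with the mean of a gene's probes, 1 and 4 with every probe, 0 and 3 with trend and robust, 5 and 1 with array weights, 4 and 0 with the replicate, 7 and 2 with the slide and 9 and 1 with the scan day block, 3 and 5 with the unnamed probes added and 6 and 2 without the arrays numbered 3, and 3 and 0 of 112 with only the groups compared and 3 and 1 of 135 with the filter on all 12 arrays. Among the gains was cholesterol synthesis in the difference (0.47, adjusted p = 0.00304 with the slide and 7.14e-04 with the scan day block). Signal over background limits what can be tested: a gene dim in 1 group has only a bound, and 28446 probes have no name.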

Other observations

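The tests of wild-type RNA in the ΔC samples numbered 3 and of the culture of origin were chosen only after the results were seen, whereas the test of scan day and slide and all list tests were planned.

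Several lists belong to no question of the design. Of 26 endoplasmic reticulum chaperones, 1 fell (2 rose and 9 fell adjusted over the list alone) in wild-type cells, with a median log2 fold change of -0.29 (camera adjusted p = 0.0404, adjusted p = 0.264 with an estimated correlation, adjusted p = 0.069 with the replicate number as a block), and this call was also lost without wild-type untreated 1 (0.069), wild-type untreated 2 (0.0575), wild-type poly(I:C) 3 (0.179), ΔC untreated 1 (0.0538) or ΔC untreated 3 (0.069), and with median scaling (0.204), quantile normalization (0.109), slide (0.0565) or scan day (0.0743) as a block. Of 43 extracellular matrix genes, 4 were higher and 12 were lower (5 and 14 adjusted over the list alone, 7 higher with the replicate number as a block) between untreated genotypes, with a median log2 difference of -0.60 (camera adjusted p = 0.0402, adjusted p = 0.86 with an estimated correlation, adjusted p = 0.153 with the replicate number as a block), and this call was also lost without wild-type untreated 3 (0.151), wild-type poly(I:C) 3 (0.0542) or ΔC untreated 2 (0.284), and with normexp (0.0908), slide (0.0944) or scan day (0.0567) as a block. After poly(I:C), 3 were higher and 10 were lower (5 and 15 adjusted over the list alone, 9 higher with the replicate number as a block), with a median of -0.54 (camera adjusted p = 0.0187, adjusted p = 0.835 with an estimated correlation, adjusted p = 0.0777 with the replicate number as a block), lost without wild-type poly(I:C) 3 (0.0542) or ΔC poly(I:C) 2 (0.17) and with slide (0.294) or scan day (0.133) as a block. Of 25 genes of cholesterol synthesis, 5 were higher and 1 was lower (5 and 1 adjusted over the list alone) between treated genotypes, with a median of 0.34 (camera adjusted p = 0.0236, adjusted p = 0.86 with an estimated correlation), lost without ΔC poly(I:C) 1 (0.0891) and with median scaling (0.053) or the mean of a gene's probes (0.0513). Between untreated genotypes 26 glycolysis and hypoxia genes had a median of -0.38 (camera adjusted p = 0.0128, adjusted p = 0.457 with an estimated correlation), lost without ΔC untreated 3 (0.0976) and with median scaling (0.0508), quantile normalization (0.22) or scan day as a block (0.0667), and 24 NRF2 targets of -0.38 (camera adjusted p = 0.00769, adjusted p = 0.219 with an estimated correlation and 0.0835 with quantile normalization). Of 22 imprinted genes, 10 were higher and 2 were lower (10 and 2 adjusted over the list alone) between untreated genotypes, with a median of 0.83 (camera adjusted p = 0.00697, adjusted p = 0.43 with an estimated correlation), lost without ΔC untreated 3 (0.0581) and with array weights (0.0521), and 9 were higher and 2 were lower (10 and 3 adjusted over the list alone) between treated ones, with a median of 0.73 (camera adjusted p = 0.0245, adjusted p = 0.491 with an estimated correlation), lost without ΔC poly(I:C) 3 (0.0561) and without the arrays numbered 3 (0.0583). Dlk1 was higher by 6.55 and Gatm was lower (-4.78) between untreated genotypes. Macrophage and leukocyte markers had a median of 0.14, or 0.13 with 2 members at the bound in the ΔC response (camera adjusted p = 0.0282, adjusted p = 0.173 with an estimated correlation), lost without wild-type poly(I:C) 3 (0.0542), ΔC untreated 1 (0.0538), ΔC untreated 2 (0.0934) or ΔC poly(I:C) 1 (0.0553) and with quantile normalization (0.0895), every probe (0.0531), no filter (0.0503), the filter on all 12 arrays (0.339) and only the groups compared (0.0567), where Cd52 was at least 10.54-fold higher.

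The 75 ribosomal protein genes had medians of -0.15 in wild-type cells (camera adjusted p = 0.0158, adjusted p = 0.901 with an estimated correlation), lost without wild-type untreated 3 (0.748) or wild-type poly(I:C) 3 (0.872), and of 0.08 in ΔC cells, or -0.06 with each array scaled to its median (camera adjusted p = 0.0068, adjusted p = 0.901 with an estimated correlation), lost without ΔC untreated 2 (0.206), ΔC untreated 3 (0.0809) or ΔC poly(I:C) 2 (0.31) and called in the opposite direction with the slide block (-0.113, adjusted p = 1.11e-04) and the scan day block (-0.0727, adjusted p = 0.0247), while in each response 0 passed limma's gene test and 0 had an unadjusted p under 0.05. Between untreated genotypes 28 were lower (52 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 4.01e-13, adjusted p = 0.562 with an estimated correlation), and -0.0027 with quantile normalization (adjusted p = 0.393), and between treated ones 6 were lower (3 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 1.34e-04, adjusted p = 0.86 with an estimated correlation), and 0.00735 with quantile normalization. For 9 lists camera made no call in any of the 5 comparisons, with a lowest adjusted p of 0.342 for eIF2α kinases and phosphatase subunits, 0.0595 for p53 targets, 0.149 for the cell cycle, 0.837 for heat shock, 0.393 for endothelial, 0.332 for epithelial, 0.56 for muscle, 0.375 for neural and 0.713 for adipocyte and chondrocyte markers. Leaving out 1 array brought a call for p53 targets and the cell cycle: p53 targets in wild-type cells without wild-type untreated 2 (0.030) and in ΔC cells without wild-type untreated 3 (0.0318), ΔC untreated 2 (0.0286) or ΔC poly(I:C) 1 (0.0248), the cell cycle in wild-type cells without wild-type untreated 3 (0.0119) and in the difference without wild-type untreated 3 (6.35e-04), ΔC untreated 2 (0.0347) or ΔC poly(I:C) 1 (0.0484). Some other alternatives, such as median scaling (0.0423 in wild-type and 0.0316 in ΔC cells), also brought a call for p53 targets.

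The arrays numbered 3 responded less in both genotypes: the median response of interferon-stimulated genes was 5.19, 5.61 and 3.91 on the wild-type arrays numbered 1 to 3 and 2.83, 2.89 and 1.68 on the ΔC arrays.

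HOX genes and Y-linked genes parted the genotypes. Of the Y-linked genes, 2 of 3 were lower in untreated ΔC cells (3 adjusted over the list alone and 3 with the replicate number as a block), with a median of -6.77 (camera adjusted p = 0.024, adjusted p = 0.476 with an estimated correlation), and 3 of 3 in treated ones, with a median of -6.75 (camera adjusted p = 0.0245, adjusted p = 0.476 with an estimated correlation, 0.0727 with slide and 0.0649 with scan day as a block and 0.0965 with no filter). Ddx3y and Eif2s3y read -2.08 and -0.335 in untreated ΔC 3, against -8.22 and -5.8 in ΔC 1 and -8.3 and -8.45 in ΔC 2, and neither of the 2 probes of Xist was well above background on any array.

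Within the slide (2 arrays) and within the scan day (3 arrays) that held both untreated groups, 27 HOX genes kept their sign at a log2 size over 1. All HOX genes tested, called or not, had a median of 2.48 and 2.45 there, which argues against scan day or slide as the cause. Wild-type RNA in untreated ΔC 3 would bring all wild-type transcripts at the share of Ddx3y (15.7% of the wild-type level) and Eif2s3y (21.1%), or of Uty (6.51%, not well above background in any untreated ΔC sample), and 26 genes at least 64 times lower in ΔC 1 and 2 lay at a median of 1.69%, with Ppp1r15a at 0.252 and Hoxd13 at 0.114%, which excludes it. A different embryo or culture in place of the allele may account for the pattern and cannot be told apart from the allele, because genotype and culture coincide in this design: 27 HOX genes were called the same way without and with poly(I:C), which either would give. Cultures of mixed or different sex, as the Y-linked levels of ΔC 3 leave open, were not tested, and the other differences between genotypes carry the same limit.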
